A study of Oryza sativa with 6 samples.

How the data were processed

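Total RNA, about 5 µg per library, was made into small RNA libraries with a TruSeq kit and sequenced on an Illumina instrument, per the labels' protocols. The deposited table gives expected counts of reads per mature sequence and precursor, and a normalized value beside each. Per the file headers, the raw expected count is the number of reads, and sequences fall into classes by mapping. One class matches rice precursors of miRBase placed on the genome, another matches only mature microRNAs of other plants, and the last holds candidates with predicted genome hairpins. The aligner, its version and the genome build are not given in the sources used here. The authors' normalized signal equals the raw value multiplied by 1 factor per library, and the rule behind that factor is not given in the sources used here. A second sheet repeated the candidates and was not used here.

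Dark columns are headed with 1 h although the sample titles give 5 days. They were assigned by the letter for dark and the repeat number, which match 1 title each.

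The 793 deposited rows hold 645 distinct sequences, 100 of them on several rows with equal values. The plan assumed that each such row repeats all reads of its sequence. Instead, of the values above 0 of sequences on 2 rows, 41.0% were whole as deposited and 84.3% after multiplying by 2, against 84.4% for sequences on 1 row (tolerance 0.0001). For the sequence on 10 rows the shares were 16.7% and 100%. For sequences on 3 to 9 rows at most 46.4% became whole, so how their reads were divided is less clear. Rows were summed per sequence, except for arm ratios. Summing counts each read once if rows hold equal shares, and using 1 row per sequence was added as an alternative after seeing the data. Sums were rounded to whole numbers for count tests.

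Libraries were compared as 3 dark against 3 light. Sequences, and known sequences summed per family, were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are light over dark. CPM values are TMM-scaled unless called unscaled. Fixed lists of families were tested with camera at a preset correlation of 0.01 for lists with at least 3 tested sequences. Length shares were tested by exact permutation. Arm ratios were log2 ratios of 5p to 3p values with 0.5 added, tested with limma 3.58.1. Each arm entered with the value of its single row at the locus, not with summed rows. Hairpins needed a total of at least 20 per arm over all libraries in these values. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.

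The lists, tests and alternatives were fixed before the data were examined. The rule for named sequences took known sequences past the threshold with groups that do not overlap. With fewer than 5 in a direction, it took up to 5 with the smallest p, named as not past the threshold. It also took the 5 most abundant known sequences, families of the lists with at least 10 unscaled CPM, predicted candidates past the threshold and hairpins past the threshold. Alternatives included DESeq2 1.42.0, limma voom, limma on the authors' normalized values, other scalings and filters, a replicate block and leaving out each library. The filter was applied anew when a library was left out, so the tested sequences of a list can then differ. Alternatives chosen after seeing the data were 1 row per sequence, leaving out sequences listed under other plants' names, and a term for libraries holding Brassicaceae-named reads.

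No pair of libraries held identical values, and chi-square per degree of freedom ranged from 33.8 to 261 over pairs. Listed reads per library ranged from 231646 to 900281. Methods were tested on simulated counts drawn from the mean abundances and totals of these libraries. All sequences and families shared the same dispersion, the median over sequences, and arm ratios used a smaller one. Sequences were drawn independently, so list members did not vary together. The rates below hold for these settings and can differ from those of the real data. With 200 changed sequences, edgeR called 10.6% of 2-fold, 60.8% of 4-fold and 94.5% of 8-fold changes. For families it called 5.26%, 46.7% and 90.3%, and for arm ratios limma called 14.6%, 56.4% and 91.1%. A list lowered 2-fold was called in 8 of 10 simulations. Reads from members of a family with near-identical sequences may be divided between them by the authors' mapping, so single members are less certain than family sums. These sums add both arms of a hairpin where both are listed, so they do not measure the targeting arm alone.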

Results

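Small RNA libraries were compared between mesocotyls of rice seedlings kept in the dark and mesocotyls of dark-grown seedlings moved to light. The mesocotyl is the stem segment between the seed and the coleoptile node, which elongates in darkness. Seedlings of the indica cultivar P25 were grown at 30 °C in the dark for 5 days, and 3 libraries were made at that point. A further 3 libraries were made after 1 h of light. The labels call these individual repeats without naming separate plants or pools, so p-values measure the spread between these libraries, part of which may be technical. The reads listed as microRNAs or microRNA candidates numbered 339119, 536423 and 636253 in dark replicates 1, 2 and 3. They numbered 231646, 900281 and 465430 in light replicates 1, 2 and 3. These totals cover listed sequences only and are not the sequencing depth. A count of 0 allows up to 3 reads, which is 3.33 unscaled CPM (reads scaled to a common library total) in light replicate 2 and 12.95 in light replicate 1. These floors cover counting error only and lack the TMM scaling of other CPM values.

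A few sequences held a large part of the listed microRNA reads. With the rows of each sequence summed, osa-miR156a, of the family that targets SPL transcription factors, held 17.7% of listed reads on average over the 6 libraries. It was followed by osa-miR396e-5p, of the family that targets growth-regulating factors, with 14.5%, and by osa-miR166a-3p, of the family that targets class III HD-ZIP transcription factors, with 12.2%. The next were peu-miR2916_R-4_1ss6AG with 5.40% and osa-MIR529a-p5 with 4.61%. The former is listed under another plant's name and without a position on the rice genome, so its origin as a rice microRNA is uncertain. This order depends on the summing: with 1 row per sequence osa-miR396e-5p came first with 13.5%, followed by peu-miR2916_R-4_1ss6AG with 9.89%, and osa-miR156a, which stands on 9 rows, had 3.64%. The log2 fold changes of these 5 sequences, light over dark, were 0.17 (SE 0.24), -0.04 (SE 0.17), -0.31 (SE 0.30), 0.23 (SE 0.61) and -0.48 (SE 0.42). None passed the test. The signs of the first 4 changed under alternatives, and without light replicate 1 osa-MIR529a-p5 was -0.09. The share of peu-miR2916_R-4_1ss6AG varied between libraries of the light group, from 18004 CPM in replicate 2 to 100929 CPM in replicate 1. Light replicate 1 also had the lowest mean correlation with the other libraries, 0.863.

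The comparison of dark with 1 h of light asks which microRNAs differ shortly after the first light. The microRNAs tied to phosphate and sulfate supply had lower values in the light libraries, except that the sum of miR827 had no stable direction. All 8 tested sequences of miR395, miR399 and miR827 had negative log2 fold changes, with a median of -1.33. They include both arms of a hairpin, such as osa-MIR395m-p5 and osa-miR395b_L-1 of osa-MIR395m, so they are not 8 separate microRNAs. In 5 of the 8, every light library lay below every dark library. The list passed edgeR-based camera with a preset correlation of 0.01 (adjusted p = 1.09e-07), and did not pass with an estimated correlation (adjusted p = 0.11). No member passed at a false discovery rate of 0.05, either over all sequences or adjusted over the list alone. Summed miR399, a family that targets a phosphate-signalling ubiquitin conjugase, had 256 ± 122 CPM in the dark and 44.6 ± 4.35 CPM in the light (SD, n = 3 each). These values rest on few reads, 84, 64 and 228 in the dark and 10, 47 and 21 in the light libraries. In light replicate 1 all 10 were of osa-MIR399d-p5. The log2 fold change of miR399 was -2.51 (SE 0.59), with an edgeR adjusted p of 0.235. DESeq2 gave an adjusted p of 0.00896 and edgeR without dark replicate 2 gave 0.0251. Over all alternatives its adjusted p reached 0.988, without dark replicate 3, and its log2 fold change was as weak as -1.39, with a term for the libraries that hold Brassicaceae-named reads. Summed miR395, which targets ATP sulfurylases and a sulfate transporter, had 395 ± 170 CPM in the dark and 133 ± 9.26 CPM in the light (SD, n = 3 each), a log2 fold change of -1.58 (SE 0.49) with an edgeR adjusted p of 0.558. Summed miR827 had a log2 fold change of -0.52 (SE 0.66), which was 0.0085 without light replicate 2 and 0.23 with the term for Brassicaceae-named reads. It had 1637 CPM in light replicate 1, above dark replicates 2 and 3 with 810 and 1243 CPM.

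**Figure D1:**
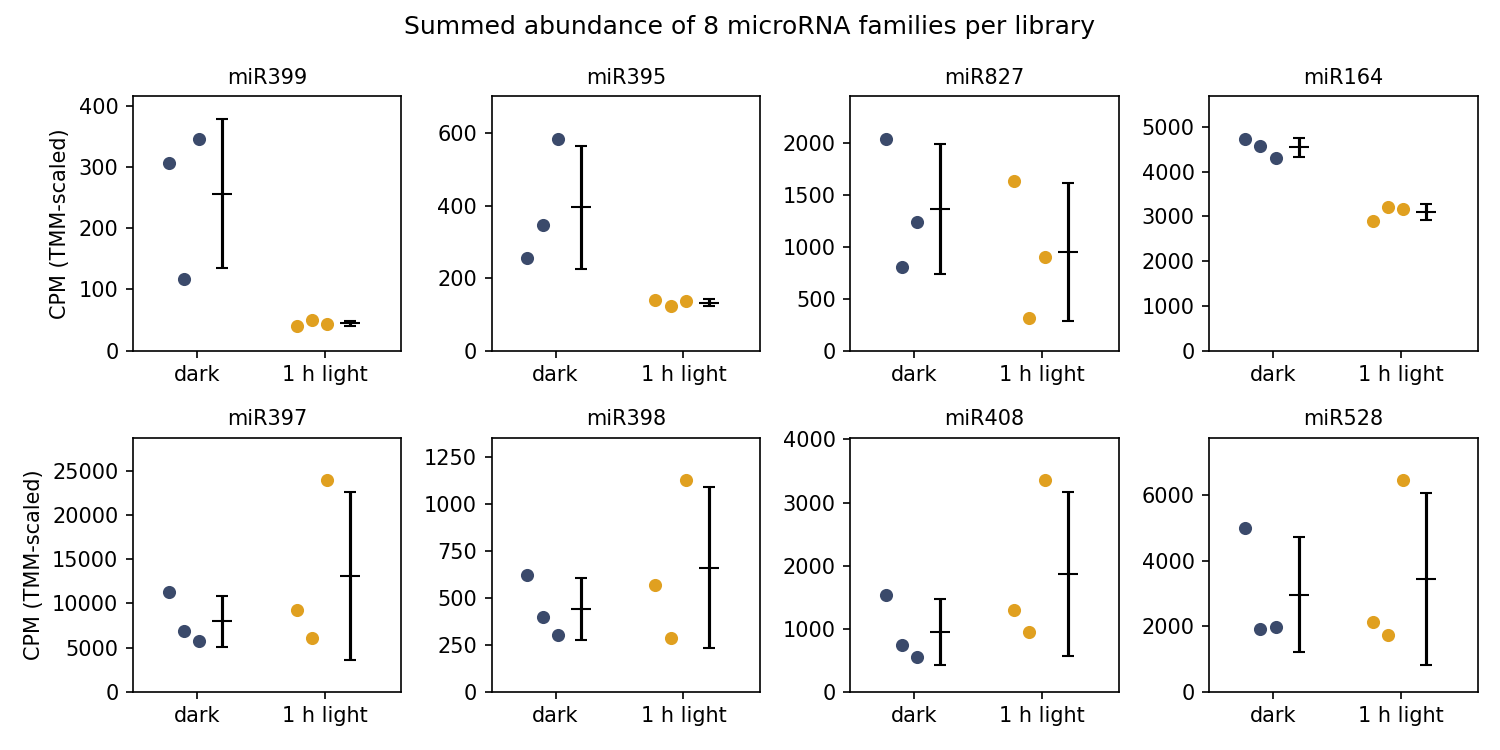
Summed abundance of 8 microRNA families in TMM-scaled CPM (vertical axes, from 0) in the dark and 1 h light libraries. Points are single libraries and bars give the mean and SD of 3 libraries. The 3 light libraries of miR399 and miR395 lie below the dark libraries, and light replicate 3 is the highest library for miR397, miR398, miR408 and miR528.

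The copper-related microRNAs, which target laccases and other copper proteins, were high in 1 light library. Of 10 tested sequences, 9 had positive log2 fold changes, with a median of 0.69, and camera gave an adjusted p of 0.0453 with the preset correlation. The adjusted p was 0.658 with an estimated correlation, and no member passed over all sequences or adjusted over the list alone. Without light replicate 3 the median was -0.23, with an adjusted p of 0.513. Without dark replicate 2 or dark replicate 3 the list did not pass either, with adjusted p of 0.313 and 0.574. The unscaled CPM of miR397 was 24925 in light replicate 3, against 9765 and 6457 in light replicates 1 and 2. In dark replicates 1, 2 and 3 it was 9103, 7019 and 5969. For miR408 it was 3498, against 1368 and 1006, and 1247, 757 and 577 in the dark replicates. The family log2 fold changes were 0.72 (SE 0.52) for miR397, 0.59 (SE 0.62) for miR398, 0.98 (SE 0.63) for miR408 and 0.22 (SE 0.61) for miR528. Without light replicate 3 these were 0.02, 0.02, 0.34 and -0.53. No sequence of miR857 was listed.

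Among families that target growth-related transcription factors, no family or sequence passed. Of 71 tested sequences of miR159, miR164, miR166, miR169, miR171, miR319 and miR396, 53 had negative log2 fold changes, with a median of -0.23. The list passed camera with the preset correlation (adjusted p = 0.00104) and not with an estimated correlation (adjusted p = 0.206). It did not pass without dark replicate 1 (adjusted p = 0.107), and without light replicate 1 its median was -0.11. No member passed over all sequences or adjusted over the list alone. Summed miR164, which targets NAC transcription factors, had 4541 ± 211 CPM in the dark and 3091 ± 177 CPM in the light (SD, n = 3 each), a log2 fold change of -0.55 (SE 0.30). Summed miR166 had a log2 fold change of -0.42 (SE 0.23), miR169 of -0.38 (SE 0.35), miR319 of -0.30 (SE 0.29) and miR396 of -0.21 (SE 0.16). The values for miR159 and miR171 were -0.13 (SE 0.22) and -0.06 (SE 0.28). Without dark replicate 2 the value was -0.35 for miR164, -0.01 for miR396, 0.05 for miR159 and 0.19 for miR171, and without light replicate 1 it was -0.13 for miR166. The sign also changed for miR169 without dark replicate 1 (0.02) and for miR319 without light replicate 2 (0.09).

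**Figure D2:**
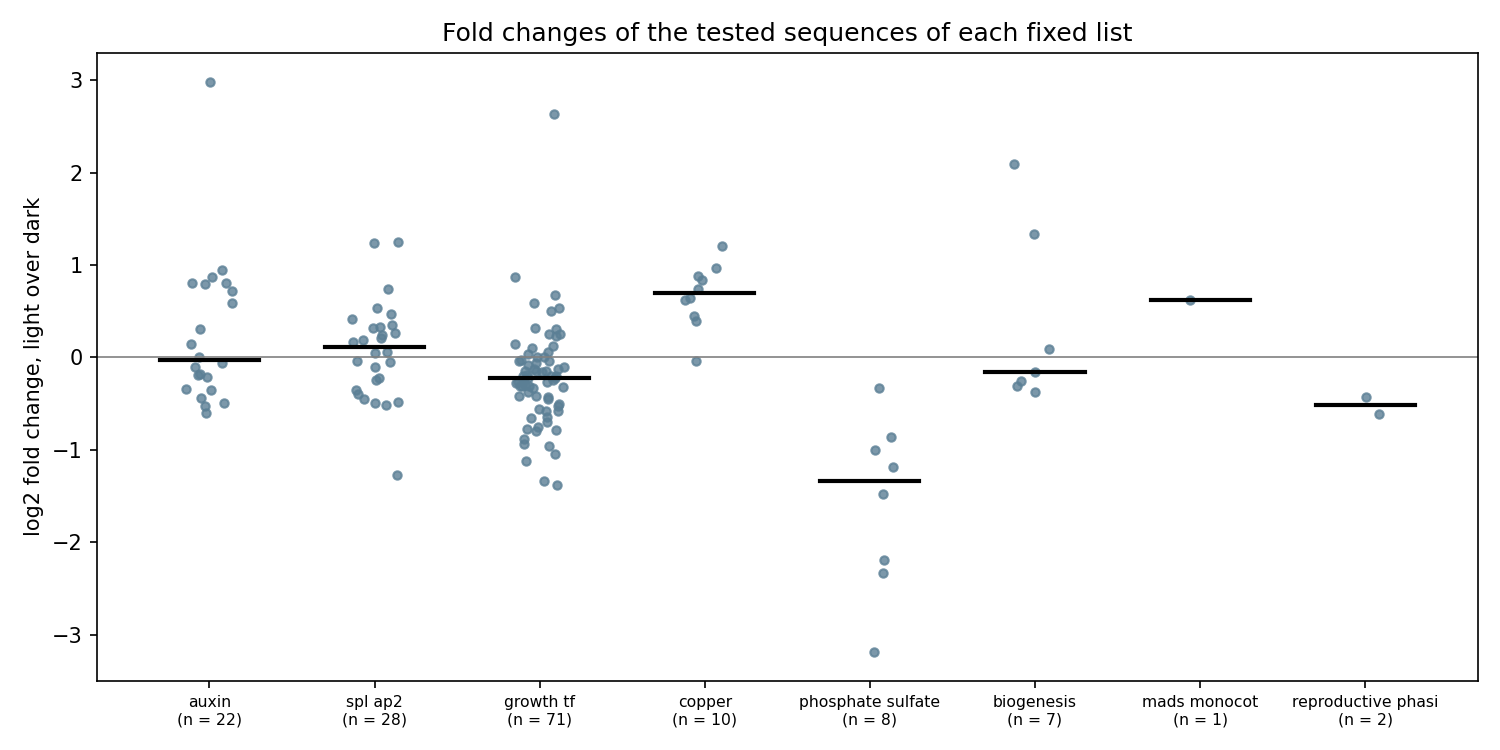
Log2 fold change, light over dark (vertical axis), of each tested sequence in the 8 fixed lists (horizontal axis, with the number of sequences). Points are sequences and black lines are list medians. All 8 phosphate and sulfate sequences lie below 0.

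The remaining lists did not pass. The auxin-related list of miR160, miR167, miR390 and miR393 had 11 sequences with positive and 11 with negative log2 fold changes, and an adjusted p of 0.385. Its median was -0.03, its mean was 0.25 and camera's direction was up. When 1 library was left out the median was 0.0013 to 0.29. The list of miR156, miR172, miR529 and miR535 had 16 positive and 12 negative values, a median of 0.11 and an adjusted p of 0.727. Within it, summed miR529 had a log2 fold change of -0.61 (SE 0.30), and of -0.32 without light replicate 1. With families as units, camera's direction was down for both lists, with medians of -0.16 and -0.25. The list tied to small RNA biogenesis, miR162, miR168 and miR403, had 3 positive and 4 negative values and an adjusted p of 0.659. Its median was -0.16, its mean was 0.35 and camera's direction was up. Without sequences listed under other plants' names the median was -0.25, the mean was -0.19 and the direction was down. Summed miR168, of the family that targets AGO1, had a log2 fold change of -0.46 (SE 0.24), and of -0.23 without dark replicate 1. This sum holds both arms and does not measure the targeting arm alone. Over all libraries osa-MIR168a had 59245 reads of the 5p arm and 84114 of the 3p arm. Part of this list carries names of Brassicaceae plants: aly-miR168a-5p and bna-miR403 had 0 reads in dark replicates 1 and 3, and 50 and 16 reads in dark replicate 2. No member of these 3 lists passed over all sequences or adjusted over the list alone. The single miR444 sequence and the 2 tested miR2118 sequences were too few for camera. The miR2118 family, a trigger of phased small RNAs in reproductive tissue, was planned as a marker of another tissue. Its sum had a log2 fold change of -0.73 (SE 0.52), and of -0.29 without light replicate 2. Most of its reads were of the 18 nt osa-MIR2118e-p5_2ss12TA18CT, with 418, 424 and 481 in the dark and 144, 295 and 421 in the light. The tested 22 nt sequence, osa-miR2118d_1ss17TA, had 6, 22 and 24 reads in the dark and 5, 36 and 5 in the light. The sum thus mostly follows the 18 nt sequence and cannot serve as a marker of the trigger.

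No single sequence passed the test. Of 289 sequences tested with edgeR, 262 known and 27 predicted candidates, 0 had a false discovery rate under 0.05, and 8 had an unadjusted p under 0.05, where 14.4 would arise by chance. DESeq2, limma voom and limma on the authors' normalized values also gave 0 sequences, with 14, 11 and 19 at an unadjusted p under 0.05. All light libraries lay above all dark libraries in 9 sequences and below in 14, together 7.96% of those tested, where chance gives 10%. The median SE of a log2 fold change was 0.60. In simulated data with 20 changed sequences, the test called 0% of 2-fold, 16.7% of 4-fold and 81.5% of 8-fold changes. Leaving out dark replicate 2 gave 4 sequences, all with Brassicaceae names.

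The known sequences with the smallest p are named here as not past the threshold, all with an edgeR adjusted p of 0.948. Lower in the light were osa-miR399d_L+1R-1 (log2 fold change -3.19, SE 0.97), osa-miR164e (-0.96, SE 0.33), osa-miR395b_L-1 (-1.19, SE 0.44), osa-MIR395m-p5 (-1.48, SE 0.56) and osa-miR171c-5p (-0.94, SE 0.40). In these 5, every light library lay below every dark library. The light values of osa-miR399d_L+1R-1 rest on 0, 5.5 and 3.5 reads in replicates 1, 2 and 3, near the 3 reads that a count of 0 allows. Higher in the light were osa-MIR171g-p3 (2.64, SE 0.96), osa-MIR1850-p3 (1.56, SE 0.60), zma-miR156i-3p_1ss13AG (1.24, SE 0.51), gma-miR6300_R+6 (1.39, SE 0.62) and osa-MIR167j-p3 (2.99, SE 1.42). Among these, only osa-MIR1850-p3 had all light libraries above all dark libraries. The log2 fold change of osa-MIR171g-p3 was 1.42 and that of gma-miR6300_R+6 was 0.89 without light replicate 1, that of osa-MIR167j-p3 was 0.53 without light replicate 2, and that of osa-MIR1850-p3 was 0.92 without light replicate 3. With the term for Brassicaceae-named reads that of osa-miR171c-5p was -0.39. For osa-MIR167j-p3 the light libraries had 144, 1120 and 14.2 CPM. The precursor of osa-miR399d_L+1R-1 was placed on chromosome 6 from 1115034 to 1115319, that of osa-miR164e on chromosome 3 from 10634119 to 10634250 and that of osa-MIR1850-p3 on chromosome 5 from 23963319 to 23963477. The genome build of these positions is not given in the sources used here.

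Summing reads per family gave 94 tested families, of which 0 passed with edgeR and 2, miR399 and miR395, had an unadjusted p under 0.05. DESeq2 passed 1 family, miR399, while limma voom and limma on the authors' normalized values passed 0. Without dark replicate 2, edgeR passed 5 families, miR158, miR399, miR824, miR1885 and miR5654. All of these but miR399 hold only sequences with Brassicaceae names and had 0 CPM in dark replicates 1 and 3. Leaving out dark replicate 2 removed the only dark library that held them.

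Read length was mostly 21 nt. These reads made up 69.4 ± 3.70% of listed reads in the dark and 63.2 ± 5.68% in the light (SD, n = 3 each). The difference of -6.26 percentage points was -2.99 without light replicate 1, which had 56.6%. The 22 nt share was 6.87 ± 0.62% in the dark and 8.83 ± 0.49% in the light (SD, n = 3 each), with every light library above every dark library. The two-sided exact permutation test gave p = 0.1 for 22 nt, the smallest that 3 against 3 allows, and 0.4 after adjustment over the 5 lengths. The 24 nt share was 0.61 ± 0.19% in the dark and 0.98 ± 0.52% in the light (SD, n = 3 each), with an exact p of 0.4. The difference of 0.37 percentage points was 0.091 without light replicate 2, which had 1.54%, and light replicate 3, with 0.51%, lay below dark replicates 2 and 3. With 1 row per sequence the difference was 3.26 for 22 nt and 0.66 for 24 nt.

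**Figure D3:**
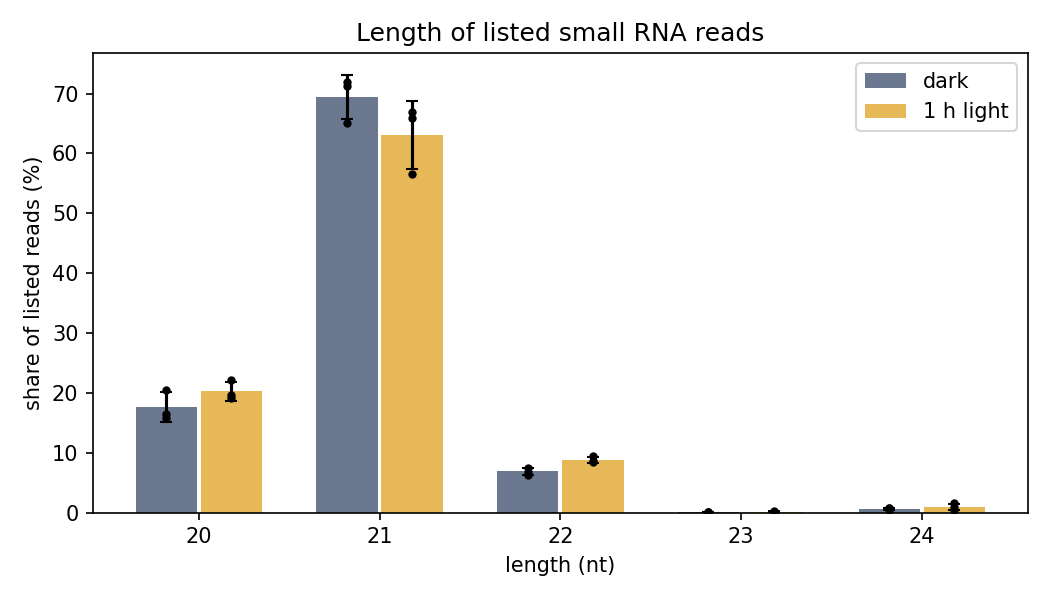
Share of listed reads (vertical axis, percent) by length (horizontal axis, nt) in the dark and 1 h light libraries. Bars are means of 3 libraries with SD, and points are single libraries. The 22 nt share of each light library exceeds that of each dark library.

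Arm use did not differ detectably. Of 201 hairpins with both arms listed, 135 had enough reads to test, and 68 gave mostly 5p and 67 mostly 3p reads. The same arm was ahead in every library in 94 of the 135. These tallies use 1 row per arm, so they depend on how reads were divided between rows. Some sequences are an arm of several hairpins, such as osa-miR156a in osa-MIR156a and osa-MIR156d, so the ratios are not independent. In limma, 0 hairpins passed at a false discovery rate of 0.05 and 1 had an unadjusted p under 0.05. Without dark replicate 2, osa-MIR827 passed. It was named after its value was seen.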

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

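One row per sequence, leaving out other plants' sequences and the term for Brassicaceae-named reads were chosen after the result was seen. That term leaves 1 dark library, assumed to vary like the others, to compare with the light ones. The cause was not tested for any change below, except where fewer libraries or another threshold define it. Listed depth differed 3.89-fold between libraries and limits sequences of low abundance. The count of 0 sequences past the threshold became 6 with an unadjusted p under 0.05 and a 2-fold change, and 0 to 4 when 1 library was left out (4 without dark replicate 2, all Brassicaceae-named). The count of 0 families became 2 with the unadjusted rule and 1, miR399, with DESeq2. It was 0 to 5 when 1 library was left out, with miR158, miR399, miR824, miR1885 and miR5654 without dark replicate 2. All of these families but miR399 are Brassicaceae-named. The arm count was 0 to 1, with osa-MIR827 without dark replicate 2. The count of 3 lists became 0 with an estimated correlation and 0 with fry.

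With an estimated correlation, the growth list (median -0.23), the copper list (0.69) and the phosphate and sulfate list (-1.33) lost their calls, with adjusted p of 0.206, 0.658 and 0.11. With fry these were 0.113, 0.746 and 0.0891. The adjusted p of the phosphate and sulfate list ranged from 4.38e-11 to 0.11 over its alternatives, with a median of -1.66 to -0.99. With families as units the copper median was 0.65 and no longer passed, and the miR156, miR172, miR529 and miR535 list had a median of -0.25. The term for Brassicaceae-named reads gave the auxin list 0.048. Leaving out 1 library gave medians of 0.0013 to 0.29 for auxin, -0.10 to 0.19 for the miR156 list, -0.36 to -0.11 for growth (no call without dark replicate 1), -0.17 to 0.10 for biogenesis and -0.23 to 1.15 for copper (no call without dark 2, dark 3 or light 3).

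Same-numbered libraries had correlations of 0.08, 0.11 and -0.24 in their deviations from group means, so the numbers share no evident pairing. No library correlated best with its own number. The highest correlations were 0.49 for dark replicate 3 with light replicate 2 and 0.38 for dark replicate 1 with light replicate 3. With the replicate block 0 sequences, 0 families and 0 arm ratios passed, and the copper list (0.37) no longer passed; no other list call changed. Length differences, in percentage points, were -8.39 to -2.99 for 21 nt, 1.67 to 2.28 for 22 nt and 0.091 to 0.60 for 24 nt when 1 library was left out.

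Upper quartile scaling shifted the median of all sequences by -0.22. Several values that were never past the threshold changed sign. For sequences these were osa-miR156a with upper quartile scaling (-0.025) and peu-miR2916_R-4_1ss6AG with the authors' values (-0.038 with either pseudocount) and voom (-0.10). Leaving out 1 library gave -0.10 to 0.063 for osa-miR396e-5p, -0.49 to 0.020 for osa-miR166a-3p and -0.31 to 0.68 for peu-miR2916_R-4_1ss6AG. For families, miR171 was 0.0093 with DESeq2, 0.0095 with RLE, 0.082 with no scaling factors, 0.013 without a filter and 0.019 with 10 counts in 3 libraries. For miR162 the values were 0.013 with DESeq2, 0.014 with RLE and 0.051 with no scaling factors. Upper quartile scaling gave miR156 -0.0090, no scaling factors gave miR159 0.0053, and the term for Brassicaceae-named reads gave miR827 0.23. Leaving out 1 library gave -0.13 to 0.072 for miR159, -0.32 to 0.17 for miR160, -0.094 to 0.11 for miR162, -0.55 to 0.024 for miR169, -0.29 to 0.19 for miR171, -0.45 to 0.091 for miR319, -0.59 to 0.45 for miR390, -0.53 to 0.82 for miR528, -0.46 to 0.055 for miR535 and -1.10 to 0.0085 for miR827. Of 311 values of named sequences under alternatives, 301 kept their direction and side of the threshold, as did 454 of 486 for families.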

Other observations

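All tests of explanations here, and the limits they are held to, were chosen after the results they bear on were seen. The first base of listed reads differed by length. Among 21 nt reads, 77.6 ± 4.40% in the dark and 80.2 ± 2.86% in the light began with U (SD, n = 3 each). Among 24 nt reads, 57.3 ± 10.1% and 54.6 ± 14.6% began with A (SD, n = 3 each), and 142 of the 170 listed 24 nt sequences did. Among 22 nt reads, 71.1 ± 1.06% and 66.5 ± 7.09% began with G (SD, n = 3 each), but only 20 of the 102 listed 22 nt sequences did.

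MicroRNAs named for Brassicaceae plants were present in 4 of the 6 libraries. Of 13 such sequences that matched without substitutions, summed reads were 0, 447 and 0 in dark replicates 1, 2 and 3, and 303, 614 and 537 in light replicates 1, 2 and 3. The sequence bra-miR158-3p had 350 unscaled CPM in dark replicate 2 and 408, 226 and 408 CPM in the light replicates. A rice sequence of the cultivar that is expressed alike everywhere would give 433.9 reads in dark replicate 3 at the lowest share of the other libraries, against 0 seen, which argues against it. Reads from a Brassicaceae source may have entered 4 libraries: all 8 sequences with at least 20 reads were at 0 in both other libraries, but the lowest Spearman correlation of their profiles between the 4 libraries was 0.31, below a limit of 0.5 that was written after the test was run, and counting names with substitutions it was 8 of 10. A rise with light stays open too, since the 833.3 unscaled CPM of dark replicate 2 lies within the light range of 682 to 1308 CPM but is 1 library.

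The lower miR395, miR399 and miR827 sequences in the light libraries were weighed against 3 technical explanations. Without the shallow light replicate 1 the list median was -1.484, over 10 sequences that then passed the filter in place of 8. The list was still past the threshold with the preset correlation, which argues against that library as the whole cause. With a term for a batch that follows the Brassicaceae-named reads, the list still passed with the preset correlation (camera adjusted p = 0.00133), with a median of -1.297 and a mean of -0.91 against -1.57 without the term. This batch stays open because the effect of light then rests on dark replicate 2 alone against the 3 light libraries. Members that vary together between libraries whatever the treatment also remain open, with an adjusted p of 0.1098 with an estimated correlation. The absolute median was 1.33 in the real split and 1.22 in the highest of the other splits. An effect of light on these microRNAs stays open as a hypothesis.

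The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split and the highest other gave 0 and 0 sequences, 0 and 0 families, 0 and 2 arm ratios, and 3 and 3 lists. For sequences, families and arm ratios the real count is 0, which 10 of 10 splits reach by construction, so these comparisons tell nothing. For lists, 2 splits, the real one included, gave as many. The other splits gave 0, 0, 2, 1, 1, 3, 2, 1 and 1 lists with camera at the preset correlation. The phosphate and sulfate list passed in the real split (camera adjusted p = 1.09e-07). It also passed in some of the others, with camera adjusted p of 0.00149, 0.00443 and 0.0376, and not in the rest. A list call at the preset correlation thus does not by itself mark the real grouping. The other split with 3 lists put dark replicates 1 and 3 with light replicate 3. The number of sequences at an unadjusted p under 0.05 was 8 in the real split and 0 to 44 in the other splits.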
